A study of Mus musculus with 5 samples.

How the data were processed

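Whole lungs of wild type and Cldn4 knockout mice were profiled by RNA sequencing, unventilated or after 2 h of ventilation at 40 cmH2O, in 5 groups. The design text gives duplicates, which makes 2 libraries per group, while the labels hold 1 record per group. The deposited data used here are 4 comparison tables over the same 21590 genes, with 0 columns of values per library. Depth per library is therefore unknown, and no replicate spread, paired analysis, label permutation or estimate of the correlation between genes could be made.

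Per the submitters' processing notes, the authors aligned reads with Bowtie 1.1.2 to the mouse build mm9 and used R 3.0.1 and edgeR, whose version they do not give. The value columns of the authors' edgeR tables are headed logFC, logCPM, PValue and FDR. The columns logFC and logCPM were read here as log2 fold changes between 2 groups and the log2 of the mean CPM over both groups, which the headers do not state. The deposited p-value of each gene and its FDR come from the authors' edgeR test, whose settings, count method and gene filter are not stated. The deposited FDR values are close to Benjamini-Hochberg values over up to 21806 genes, slightly more than each table lists. Fold changes of exactly 0 were deposited for 56, 47, 88 and 74 genes with a mean log2 CPM of at least 3 in the tables for KO_noVILI, WT_VILI, KO_VILIlow and KO_VILIhigh. They include Scgb1a1 and Sftpc in all 4 tables, so no statement on these genes is made. The printed folds of Klrg1, AI506816, Bpifa1, Prss22, Il1r2, Cxcl2, Ly6k, Ucp1 and Zfp429 include comparisons with a group at a rebuilt level under 0.5 CPM, and are fitted values, not bounds. Dates stood in place of 27 gene symbols, and genes were matched by Entrez identifier, which worked for 21534. The reference gene table was that of GRCm38.p6, another build than the authors' mm9, so only names, chromosome membership and the order of neighbouring genes were taken from it, and no coordinates are given.

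Before the data were examined, every table was planned to be read as a comparison with WT_noVILI, since the labels list that group under every file. The values contradicted this for both ventilated knockout tables. Group levels were rebuilt from fold change and mean abundance over 10562 genes, and differences were centred on their median. The median absolute difference of the reference level from WT_VILI was 0.0491 and 0.045 log2, against 0.2042 and 0.2027 log2 from WT_noVILI. Of the genes, 51.4 and 58.9 percent lay within 0.05 log2 of WT_VILI, and 13.6 percent of WT_noVILI in both. The match was closest for WT_VILI but not exact. WT_noVILI rebuilt from the unventilated knockout table and from the WT_VILI table differed by 0.0059 log2, with 99.3 percent within 0.05. Both ventilated knockout tables were therefore read as KO_VILIlow and KO_VILIhigh against WT_VILI, a change made after the data were seen.

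Genes were called at a deposited adjusted p of 0.05. The other 7 contrasts were derived by adding or subtracting the authors' deposited log2 fold changes. Each standard error was the size of the fold change divided by the normal quantile of its deposited p, the variances were summed, and Benjamini-Hochberg adjustment was made over genes with a mean log2 CPM of at least 1. These tests are approximate. In 5 of them a group cancels whose variance is still counted, which makes them conservative. In the other 2, which compare the genotype difference with and without ventilation, no group cancels and the test is not conservative. Genes named in the text follow a rule fixed before the data were examined: Cldn4, Egr1, Tnf, Il1b, Il6, Cldn3, Cldn5 and Cldn18, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1, predicted genes left out, up to 3 called members with the smallest p of each gene list, and up to 8 genes each way in derived contrasts. Genes named otherwise are sex-linked genes, members of lists given beside these, and those said to be chosen after their values were seen.

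The 33 gene lists with 912 members were fixed before the data were examined, and 13 members were absent from the tables. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 on signed normal scores of genes with a mean log2 CPM of at least 0, or at least 1 in derived contrasts, the minimum used to derive them. The preset correlation between genes was 0.01, and 0.05 as an alternative. A correlation could not be estimated without values per library. Of 363 list tests, 358 had the 5 members needed and were adjusted together. Overlaps were set beside those of independent lists and of simulated unchanged groups with a shared reference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used otherwise.

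The procedures were tested on simulated data. Of lists shifted by 1 score unit, 98.2 percent were called, and 0 percent with none shifted. The simulated scores were independent between genes, so these rates do not show how often lists of correlated genes are called falsely. Of simulated log2 changes of 1 and 2, the derived test recovered 59.0 and 99.0 percent for KO_VILIhigh against KO_VILIlow, 39.0 and 94.0 percent against KO_noVILI and 60.0 and 99.0 percent against WT_noVILI, with 0 false calls. For the test that compares the genotype difference with and without ventilation it recovered 54.0 and 93.0 percent in KO_VILIlow, with 10 false calls among 157, and 53.0 and 94.0 percent in KO_VILIhigh, with 7 among 154. Alternatives covered thresholds, abundance minimums, centring, the variance of derived contrasts, genes on X and Y and the settings of the list tests.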

Results

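Gene expression was measured by RNA sequencing in whole lungs of wild type mice and of mice lacking Cldn4, which encodes claudin-4, a tight junction protein of epithelial cells. Lungs were taken without ventilation or after 2 h of ventilation at a pressure of 40 cmH2O, a protocol that injures the lung by stretch (ventilator-induced lung injury, VILI). The 5 groups were unventilated wild type (WT_noVILI), unventilated knockout (KO_noVILI), ventilated wild type (WT_VILI), ventilated knockouts with injury similar to wild type (KO_VILIlow) and ventilated knockouts with more injury than wild type (KO_VILIhigh). The design text gives duplicates for every group, and only the authors' 4 comparison tables over 21590 genes were used here, so no value per animal, depth per library or replicate spread can be given. The study formed both knockout groups by the injury of the animals, which makes comparisons with them descriptive of lungs already sorted by outcome.

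Cldn4 itself (Entrez 12740) was checked first. Group levels rebuilt from the fold change and mean abundance in the authors' deposited tables were 8.98 CPM (counts scaled to library size, as the tables' abundance column) in WT_noVILI and 140 CPM in WT_VILI. They were 0.14 CPM in KO_noVILI, 0.0212 CPM in KO_VILIlow and 0.122 CPM in KO_VILIhigh, near the floor of the estimates, so no fold is given for the knockouts. The rise in ventilated wild type lungs was 3.96 on the log2 scale in the authors' deposited table (adjusted p = 7.17e-91). The same rebuilding showed that the groups differed in sex-linked transcripts: Xist, expressed from the inactive X chromosome of females, stood at 890 CPM in WT_noVILI and 505 CPM in KO_noVILI, against 6.13, 4.08 and 2.56 CPM in WT_VILI, KO_VILIlow and KO_VILIhigh. The Y-linked gene Ddx3y stood at 0.0984 and 0.421 CPM in the unventilated groups and at 115, 107 and 90.7 CPM in the ventilated groups. Every comparison of ventilated with unventilated lungs below therefore also compares male with female levels of these genes. Any effect of sex on other genes cannot be told apart from ventilation there.

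The comparison of unventilated knockout with unventilated wild type lungs shows how the genotypes differed at rest. It cannot separate loss of Cldn4 from other differences between the animals or the lungs taken. Stress protein genes were higher in the knockout: 13 of 25 measured heat shock genes rose and none fell in the authors' deposited table (17 adjusted over the list alone), among them the chaperones Hspa1b (log2 fold change 2.08), Hsph1 (1.58) and Fkbp4 (0.99). Interferon response genes rose in 11 of 33 cases (25 higher and 1 lower adjusted over the list alone), with Oas2 at 1.49, Igtp at 1.38 and Gbp6 at 1.37, and 7 of 30 cell cycle genes rose (12 adjusted over the list alone), with Rrm2 at 1.16. Cytokine and chemokine genes rose in 5 of 23 cases (9 adjusted over the list alone), with Ppbp at 1.87, Cxcl1 at 1.63 and Cx3cl1 at 0.97. Immediate early genes, which respond to stimuli within minutes, went the other way, with 12 lower and 2 higher of 45 (14 and 4 adjusted over the list alone): in the authors' deposited table Egr3 was at -1.74, Btg2 at -1.40 and Egr1 at -2.14. The list tests (limma) called all of these groups, with adjusted p = 8.29e-21 for heat shock, 1.55e-13 for interferon response, 6.72e-10 for cell cycle, 0.000107 for cytokines and 2.76e-06 for immediate early genes.

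Markers of cell types and neighbouring tissues also differed between these unventilated groups. Cardiac muscle genes, which heart and pulmonary vein walls express, were lower in 11 of 18 cases in the authors' deposited table (13 adjusted over the list alone), with Ryr2 at -1.43 and Myh6 at -1.38. Ciliated cell genes were lower in 8 of 30 cases (15 adjusted over the list alone), with Ccdc39 at -1.32 and Sntn at -1.24. In the list of T, B and NK cell genes 8 were lower and 4 higher of 27 (9 and 10 adjusted over the list alone), the lower ones led by the B cell genes Ms4a1 at -1.79 and Cd79a at -1.60, while Igj, the joining chain of plasma cell antibodies, rose by 2.24. Circadian clock genes were lower in 8 and higher in 1 of 21 cases (11 and 2 adjusted over the list alone), with Bhlhe41 at -1.12 and Dbp at -0.98. The list tests (limma) gave adjusted p = 8.22e-20 for cardiac muscle, 7.57e-13 for ciliated cells and 5.1e-07 for the circadian clock. Further lists were called in this table. Alveolar type 1 genes had a median of -0.32 with none of 23 called (2 lower adjusted over the list alone), and club and goblet cell genes were lower in 3 of 19 cases (4 adjusted over the list alone), with Cyp2a5 at -1.66 and Scgb3a2 at -0.68. Endothelial genes were higher in 3 of 33 cases (10 higher and 1 lower adjusted over the list alone), with Sox7 at 0.82 and Sox18 at 0.68. Genes of skeletal muscle, fat, thymus and mesothelium were lower in 4 and higher in 1 of 12 cases (5 and 1 adjusted over the list alone), with Adipoq at -1.54 and Cfd at -1.34. Their list tests (limma) gave adjusted p = 0.000928, 0.000994, 0.000226 and 0.000226 in that order. For T, B and NK cells the test did not pass (adjusted p = 0.764) and leaned down, while the median of 0.19 and mean of 0.01 were positive. In the list of tight junction genes, which leaves out Cldn4, none of 29 members passed the threshold in the authors' edgeR comparison (list test adjusted p = 0.249), and the claudins Cldn3, Cldn5 and Cldn18 stood at 0.09, 0.21 and -0.45 with adjusted p of 1, 0.684 and 0.377 in the authors' deposited table.

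The largest single rises in unventilated knockout lungs were in class I genes of the major histocompatibility complex, H2-M2 (5.18), H2-K2 (4.26), H2-Bl (3.90) and H2-T3 (3.01), with Klrg1 (3.94), Alpl (3.59), C1qtnf3 (3.32) and Tbx21 (3.04) beside them in the authors' deposited table. Reads of these H2 genes can be shared with near-identical copies, so their single values are uncertain. Strain-derived chromosome segments that differ between the animals, taken up under the other observations, may also account for them. The largest falls besides Cldn4 were in AI506816 (-4.45), Bpifa1 (-3.14), Grp (-2.42), H2-Ob (-2.29), Ttn (-2.26), Nr4a1 (-2.16) and Egr1. In all, 726 genes passed an adjusted p of 0.05 in the authors' deposited table, 312 higher and 414 lower.

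Ventilation of wild type lungs was followed by higher inflammatory, immediate early and stretch-responsive transcripts. Cytokine and chemokine genes rose in 17 and fell in 2 of 27 cases in the authors' deposited table (19 and 3 adjusted over the list alone), with log2 fold changes of 5.10 for Cxcl2, 4.65 for Il6, 3.86 for Ccl3, 3.27 for Tnf and 1.64 for Il1b. Immediate early genes rose in 27 and fell in 1 of 45 cases (30 and 1 adjusted over the list alone), among them Atf3 at 3.08 and Maff at 2.55, while the endothelial flow-responsive factor Klf2 fell by 2.42. Egr1 rose by 0.73, a call that the authors' deposited p no longer gave under Bonferroni adjustment. Stretch and YAP target genes rose in 12 and fell in 2 of 25 cases (12 and 3 adjusted over the list alone), led by the growth factor Areg at 4.44, the prostaglandin synthase Ptgs2 at 3.26 and tissue factor, F3, at 2.61. The adjusted p of the list tests was 8.6e-14 for cytokines, 2.97e-32 for immediate early genes and 4.18e-22 for stretch and YAP targets.

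Glucocorticoid-responsive genes showed the highest share of changed members after ventilation apart from the sex-linked list, with 21 of 25 higher in the authors' deposited table (21 adjusted over the list alone), including the cell cycle inhibitor Cdkn1a and the metabolic kinase Pdk4, both at 2.57, and Errfi1 at 2.03. Genes of oxidative stress and metallothioneins rose in 12 of 29 cases (14 higher and 1 lower adjusted over the list alone), with Slc7a11 at 3.48 and Mt2 at 3.26. Neutrophil genes rose in 15 and fell in 2 of 24 cases (16 and 2 adjusted over the list alone), with Il1r2 at 5.89 and Ngp at 4.14. Endothelial genes fell in 9 and rose in 2 of 33 cases (12 and 2 adjusted over the list alone), with Sox18 at -2.23, Aplnr at -1.42 and Sox7 at -1.20 in the authors' deposited table. Interferon response genes fell in 9 of 32 cases (11 lower and 1 higher adjusted over the list alone), with Iigp1 at -1.21 and Psmb8 at -0.80. Red blood cell genes fell in 7 of 10 cases (8 adjusted over the list alone), with Hbb-bs at -1.92. Ciliated cell genes fell in 4 of 30 cases (4 adjusted over the list alone), with a median of -0.31 and Foxj1 at -1.68 (list test, limma, adjusted p = 0.000452). Ribosomal protein genes fell in 9 of 40 cases (22 adjusted over the list alone), with a median of -0.33. The list tests (limma) gave adjusted p = 2.14e-49 for glucocorticoid response, 1.65e-12 for oxidative stress, 1.53e-09 for neutrophils, 4.39e-05 for endothelium, 5.84e-05 for interferon response, 1.99e-05 for red blood cells and 2.56e-06 for ribosomal proteins. Tight junction genes rose in 8 of 31 cases (10 adjusted over the list alone), with Cldn23 at 1.61, Cldn7 at 0.74 and Cldn3 at 0.50, although their list test (limma) did not pass (adjusted p = 0.0705).

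Besides the sex-linked genes, the largest rises after ventilation of wild type lungs were Prss22 (5.89), Il1r2, Cxcl2 and Il6, and the largest falls Adrb3 (-2.89), Hes2 (-2.69), Gmnc (-2.67), Meox2 (-2.66), Emr4 (-2.46) and Slc10a5 (-2.46), in the authors' deposited table. Xist and its antisense partner Tsix fell by 7.18 and 4.16. The table called 1962 genes, 1048 higher and 914 lower, of which 1907 remained after leaving out genes on X and Y.

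**Figure D1:**
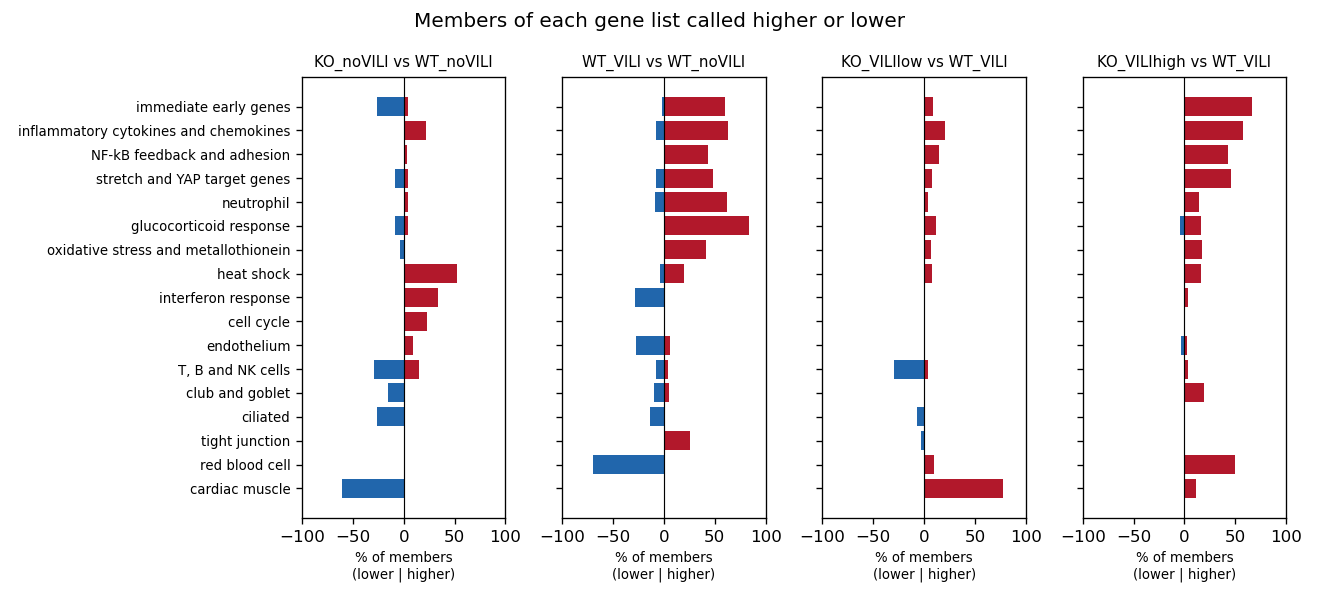
Horizontal bars show, for 17 gene lists and the authors' 4 deposited comparisons, the percent of measured members called higher (right of 0) or lower (left of 0) at an adjusted p of 0.05. Immediate early genes were called higher in 27 of 45 cases in WT_VILI against WT_noVILI and in 30 of 45 cases in KO_VILIhigh against WT_VILI.

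Knockout lungs whose injury was similar to wild type were compared with ventilated wild type lungs in a table whose reference level was closest to WT_VILI (see the processing summary). Cytokine genes rose in 6 of 29 cases in the authors' deposited table (12 higher and 1 lower adjusted over the list alone), with the platelet chemokine Ppbp at 1.99, Lif at 1.49 and Il1rn at 1.07. Ppbp was already higher by 1.87 in KO_noVILI against WT_noVILI. Immediate early genes rose in 4 of 45 cases (16 adjusted over the list alone), with Pim1 at 0.90 and Nr4a3 at 0.66. Egr1 (0.54, adjusted p = 0.798), Tnf (0.60, adjusted p = 1), Il1b (0.68, adjusted p = 0.604) and Il6 (0.76, adjusted p = 0.346) did not pass in the authors' deposited table. Cardiac muscle genes were higher in 14 of 18 cases (18 adjusted over the list alone), with Mybpc3 at 2.93, Sln at 2.09 and Tnnt2 at 1.69, and red blood cell genes had a median of 1.22 with 1 of 10 called (6 adjusted over the list alone). Neutrophil genes had a median of 0.41 with 1 of 25 called (1 adjusted over the list alone), and respiratory chain genes, a list kept for RNA quality, a median of 0.19 with none of 36 called. Among T, B and NK cell genes 8 were lower and 1 higher of 27 (10 and 1 adjusted over the list alone), with Cd79b at -1.31 and Igj at 2.31. The list tests (limma) gave adjusted p = 7.82e-13 for cytokines, 5.25e-14 for immediate early genes, 1.5e-48 for cardiac muscle, 4.31e-06 for red blood cells, 2.57e-05 for neutrophils, 0.000315 for the respiratory chain and 9.61e-13 for T, B and NK cells. Ciliated cell genes had a median of -0.25 with 2 of 30 lower (2 adjusted over the list alone), with Sntn at -1.37. Alveolar macrophage genes had a median of 0.15 with 1 of 23 higher (2 adjusted over the list alone), and genes of skeletal muscle, fat, thymus and mesothelium one of 0.44 with 1 of 16 higher (1 adjusted over the list alone). Their list tests (limma) gave adjusted p = 7.35e-05, 0.00563 and 0.00228. NF-kB feedback and adhesion genes were higher in 4 of 28 cases and lower in none (6 higher adjusted over the list alone), with Socs3 at 1.52. Stretch and YAP targets were higher in 2 of 25 cases and lower in none (6 higher adjusted over the list alone), with Ankrd1 at 1.01. The list tests (limma) of the NF-kB and stretch lists gave adjusted p = 1.98e-08 and 0.00127.

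Of 210 genes called in this comparison, 146 were higher and 64 lower in the authors' deposited table. The largest rises were BC018473 (at a rebuilt 47.5 CPM, with WT_VILI near the floor of the estimates, so no fold is given), Nptx1 (4.41), Ly6k (4.26), H2-M2 (3.75), H2-K2 (3.33), H2-Bl (3.18), Myl1 (3.01) and Mybpc3. Among the largest falls besides Cldn4 were H2-Ob (-2.43), Faim3 (-2.37), Cr2 (-2.24), Fcrla (-2.16), Cxcr5 (-2.07) and Rprml (-2.02). Besides Cldn4, which the tight junction list leaves out, 1 of its 31 members was called, Cldn8, at -1.29 in the authors' deposited table.

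Knockout lungs with higher injury had higher levels of inflammatory and immediate early transcripts than ventilated wild type lungs. Immediate early genes were higher in 30 of 45 cases in the authors' deposited table (38 adjusted over the list alone) and none was lower, with Arc at 2.53, Fosb at 2.20 and Egr1 at 2.13. Cytokine and chemokine genes were higher in 18 of 31 cases (24 adjusted over the list alone), with the monocyte chemokine Ccl2 at 3.00, Cxcl2 at 2.99, Lif at 2.56, Il6 at 2.24, Tnf at 2.01 and Il1b at 1.73. NF-kB feedback and adhesion genes were higher in 12 of 28 cases (19 adjusted over the list alone), with Socs3 at 2.18, Tnfaip2 at 1.46 and Tlr2 at 1.19, and stretch and YAP targets in 12 of 26 cases (14 adjusted over the list alone), with Plau at 2.54 and Thbs1 at 1.39 in the authors' deposited table. The adjusted p of the list tests was 9.11e-88 for immediate early genes, 4.41e-56 for cytokines, 1.69e-26 for NF-kB and 3.21e-17 for stretch and YAP targets. All of these lists were also called in KO_VILIlow against WT_VILI, with smaller medians.

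Markers of other cells moved with these groups. Neutrophil genes had a median of 0.90 with 4 of 27 called higher (14 adjusted over the list alone), and red blood cell genes were higher in 5 of 10 cases (7 adjusted over the list alone), with Alas2 at 2.26 and Hbb-bs at 1.61 in the authors' deposited table. For Alas2 and Hbb-bs this came from low levels in WT_VILI. Hbb-bs stood at a rebuilt 361 CPM in WT_VILI, against 1370 in WT_noVILI, 2540 in KO_noVILI, 1280 in KO_VILIlow and 1140 in KO_VILIhigh. In the same order Alas2 stood at 12.6 CPM, against 52.9, 91.4, 53.5 and 54.5. Club and goblet cell genes were higher in 4 of 21 cases (6 adjusted over the list alone), with the secreted defence proteins Reg3g at 3.86, Bpifa1 at 3.61 and Bpifb1 at 2.17. Cardiac muscle genes had a median of 0.81 with 2 of 18 called (3 adjusted over the list alone). The list tests passed for these 4 lists, with adjusted p of 4.66e-14, 3.1e-09, 1.55e-07 and 6.96e-08 in that order. Alveolar type 2 genes were lower in 3 of 23 cases (4 adjusted over the list alone), with Chi3l1 at -1.67 and Sfta2 at -0.92. Both were already lower in KO_noVILI against WT_noVILI, at -1.56 and -1.05, and Chi3l1 was at -1.63 in KO_VILIlow against WT_VILI. Monocyte and interstitial macrophage genes had a median of 0.30 with 2 of 24 higher (3 adjusted over the list alone), and genes of skeletal muscle, fat, thymus and mesothelium a median of 1.02 with 2 of 18 higher (6 adjusted over the list alone). Their list tests (limma) gave adjusted p = 0.00252, 0.00325 and 8.15e-05. Respiratory chain genes had a median of 0.22, and their list test (limma) lost its call at the larger preset correlation (adjusted p = 0.00399, and 0.0605 at a correlation of 0.05). Of the 31 members of the tight junction list, which leaves out Cldn4, none was called over all genes (1 adjusted over the list alone). In total 337 genes were called, 243 higher and 94 lower. Among the largest falls besides Cldn4 were Zfp429 (-4.59), Grp (-2.98), Cntn4 (-2.79), Angptl7 (-2.28), Zfp449 (-2.22) and Septin3 (-2.14) in the authors' deposited table. The largest rises besides Reg3g and Bpifa1 were BC018473, Ly6k (3.95), Ucp1 (3.89), H2-K2 (3.74), H2-M2 (3.65) and Nptx1 (3.65). BC018473 stood at a rebuilt 14.3 CPM, with WT_VILI near the floor of the estimates, so no fold is given. All of these except Ucp1, Reg3g and Bpifa1 were also among the largest rises in KO_VILIlow.

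**Figure D2:**
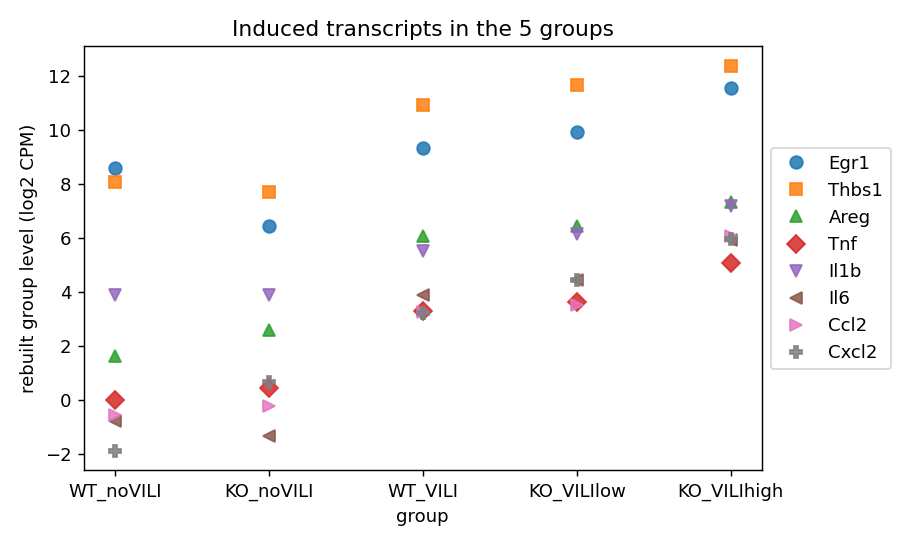
Points give the level of 8 induced transcripts in log2 CPM (vertical axis), rebuilt for each of the 5 groups (horizontal axis) from the authors' fold changes and mean abundances, with no replicate error available. Egr1 stands at 8.58 in WT_noVILI, 6.43 in KO_noVILI, 9.31 in WT_VILI, 9.93 in KO_VILIlow and 11.53 in KO_VILIhigh.

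Subtracting both knockout comparisons, which share WT_VILI, compares high with low injury among ventilated knockouts by an approximate test. It called 21 of 12696 genes, 19 higher and 2 lower in KO_VILIhigh. Higher were the chemokines Ccl2 by 2.53, Ccl7 by 2.12, Ccl3 by 1.82 and Cxcl1 by 1.69, the immediate early genes Fosb by 1.95, Fos by 1.70 and Egr1 by 1.59 (approximate standard errors 0.43, 0.46, 0.41, 0.41, 0.32, 0.31 and 0.35 in that order), and the B cell gene Fcrla by 2.67. Angptl7 and Per3 were lower, at -2.34 and -1.18. Of 45 immediate early genes 10 were higher (22 adjusted over the list alone), and of 23 cytokine genes 4 (15 adjusted over the list alone), with list tests (limma) at adjusted p = 1.54e-69 and 4.29e-34. Tnf (1.41, adjusted p = 0.804), Il1b (1.05, adjusted p = 1) and Il6 (1.48, adjusted p = 0.833) did not pass the approximate test. Neutrophil genes had a median of 0.44 with none of 24 called (1 adjusted over the list alone), and T, B and NK cell genes a median of 0.90, with list tests (limma) at adjusted p = 1.3e-08 and 9.7e-25. Club and goblet cell genes had a median of 0.83 (none of 17 called, 8 adjusted over the list alone), ciliated cell genes 0.48 (none of 28) and cardiac muscle genes -0.48 (none of 18), with list tests (limma) at adjusted p = 1.65e-16, 7.16e-10 and 9e-05. The variance of WT_VILI is counted in both errors here, which lowers the number of calls, and with variance multiplied by 0.5 the test called 133 genes.

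Within the knockout, the response to ventilation was derived by combining 3 tables. KO_VILIlow differed from KO_noVILI in 438 genes by the approximate test, 275 higher and 163 lower, and KO_VILIhigh in 485, 307 higher and 178 lower. Immediate early genes were higher in 28 and lower in 1 of 42 cases in KO_VILIlow (32 and 1 adjusted over the list alone) and in 36 and 1 of 42 in KO_VILIhigh (36 and 1). Egr1 was higher by 3.42 and 5.01, Thbs1 by 3.89 and 4.58, Atf3 by 3.92 and 5.22 and Mt2 by 5.03 and 5.39 in the low and high groups. Interferon response genes were lower in 10 of 29 and 8 of 30 cases (15 and 9 adjusted over the list alone), with Iigp1 at -2.48 and -2.33, and endothelial genes in 6 of 32 in both (7 and 9 adjusted over the list alone), with Sox18 at -2.41 and -2.55. Markers of other cells moved as well. Cardiac muscle genes were higher in 13 and 1 of 17 cases (15 and 10 adjusted over the list alone), with medians of 2.01 and 1.52. Neutrophil genes were higher in 6 and 10 of 22 cases (12 higher with 2 lower, and 16, adjusted over the list alone), with medians of 1.54 and 2.33. T, B and NK cell genes had a median of -0.85 in KO_VILIlow with 4 of 20 lower (6 adjusted over the list alone) and of -0.09 in KO_VILIhigh with 1 of 21 higher (1 adjusted over the list alone). The list tests (limma) gave adjusted p = 1.79e-68 and 3.78e-122 for immediate early genes, 7.51e-17 and 8.97e-08 for interferon response, 3.6e-07 and 2.3e-08 for endothelium, 5.75e-22 and 1.66e-08 for cardiac muscle, 8.68e-10 and 4.81e-16 for neutrophils and 1.12e-05 and 0.62 for T, B and NK cells in the low and high groups. Club and goblet cell genes were higher in 3 of 16 cases in KO_VILIhigh (5 adjusted over the list alone, list test, limma, adjusted p = 0.000316), with Bpifa1 at 9.05. Genes of skeletal muscle, fat, thymus and mesothelium were higher in 2 and 3 of 9 cases (4 and 4 adjusted over the list alone), with list tests (limma) at adjusted p = 0.000736 and 0.000546. With variance multiplied by 0.5 the counts were 1234 and 1477.

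Against unventilated wild type lungs, the derived sums called 853 genes in KO_VILIlow, 515 higher and 338 lower, and 936 in KO_VILIhigh, 557 higher and 379 lower. Il6 was higher by 5.41 and 6.89, Tnf by 3.87 and 5.28 and Cxcl2 by 6.60 and 8.09. The calls overlapped with those of ventilated wild type lungs in the same direction for 716 and 678 genes, where independent lists would share 61.5 and 67.8 and unchanged groups with a shared reference 293 and 314 in simulation. The covariance of log2 fold changes was 0.291 and 0.304 against a simulated 0.0508 and 0.0556. Both knockout responses shared 583 genes against 32.8 for independent lists and 189 in simulation, with a covariance of 0.412 against a simulated 0.0818. The shared reference could not be split between the comparisons, so its part is known only from the simulation.

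The genotype difference without ventilation shares no group with the differences among ventilated lungs. Of 655 and 185 genes called at a mean log2 CPM of 1 or more in KO_noVILI against WT_noVILI and in KO_VILIlow against WT_VILI, 74 changed in the same direction and 22 in opposite directions, where independent lists would share 4.27 and 4.80. For KO_VILIhigh the numbers were 72 and 14, against 6.98 and 7.99. Genes changed alike in all 3 of the authors' deposited tables included H2-K2 (4.26, 3.33 and 3.74), Alpl (3.59, 1.68 and 1.91), Igj (2.24, 2.31 and 2.54), Stbd1 (1.74, 2.12 and 1.94) and Chi3l1 (-1.56, -1.63 and -1.67), named after their values were seen.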

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

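All tests in this part were chosen after the results were seen, and all use approximate errors derived from the authors' deposited tables. The results stand here because the genotype difference was not alike without and with ventilation by a test of the difference itself, in which no group cancels and which on simulated data gave 10 false calls among 157 for the low group and 7 among 154 for the high group. The difference in KO_VILIlow against WT_VILI departed from that in unventilated lungs for 148 genes, and the difference in KO_VILIhigh for 201 genes. Unventilated groups had female and ventilated groups male levels of Xist and Ddx3y. Such a departure therefore cannot tell ventilation apart from animal sex. For Egr1 the departure was 2.68 in KO_VILIlow and 4.28 in KO_VILIhigh on the log2 scale. Much of it came from the unventilated lungs, where Egr1 stood at -2.14 in KO_noVILI against WT_noVILI. Against WT_VILI it stood at 0.54 in KO_VILIlow, not called, and at 2.13 in KO_VILIhigh. The median departure of immediate early genes was 0.62 and 1.15 in the low and high groups, and that of club and goblet cell genes was 0.58 in the high group, while in the low group it was 0.13 and did not pass the list test (limma, adjusted p = 0.0899). Cardiac muscle genes departed by a median of 2.58 and 1.99, and genes of skeletal muscle, fat, thymus and mesothelium by 1.17 and 0.96. The cardiac muscle median was -1.23 in KO_noVILI against WT_noVILI and 1.36 in KO_VILIlow against WT_VILI. Cell cycle genes departed by a median of -0.88 in the low group and -0.73 in the high group, though their call in KO_VILIlow against WT_VILI was lost at a preset correlation of 0.05 (adjusted p = 0.172). Ribosomal protein genes departed by 0.30 in the high group and 0.20 in the low group, and their calls without and with ventilation were lost at that correlation (adjusted p = 0.173 and 0.0658).

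Cytokine and immediate early transcripts were higher in KO_VILIhigh than in WT_VILI, a comparison in which injury was used to form the group. Red blood cell genes were higher too, with a median of 1.24 in this comparison beside 0.90 for immediate early genes, but they were as high in KO_VILIlow against WT_VILI (1.22). Hbb-bs and Alas2 stood near the level of WT_noVILI in both ventilated knockout groups and were low in WT_VILI. More blood as the whole cause would need red blood cell genes to differ between KO_VILIhigh and KO_VILIlow as immediate early genes do. Their median difference was -0.13 (upper bootstrap bound 0.11) against 0.77 for immediate early genes (lower bound 0.43), while a part from blood stays open. A difference in animal sex would move Y-linked genes and Xist in opposite directions and by the size seen between the unventilated and ventilated groups. Ddx3y stood at -0.33, and all 5 sex-linked genes, Xist among them, were negative with a median of -0.61 (list test, limma, adjusted p = 0.00531) and none called. More neutrophils as the whole cause of the cytokine part would need neutrophil genes to rise as much as cytokine genes. The median of 27 neutrophil genes was 0.90 (upper bootstrap bound 1.24) against 1.95 for 31 cytokine genes (lower bound 1.54), with genes drawn as if independent, while a part from neutrophils or a change within them stays open. This test was taken as deciding after 2 others had been seen. With the upper bound of 1.80 from S100a8 and S100a9 alone, the lower bound of 1.54 did not pass, but bounds of single genes and of a list median are not alike. The 18 called cytokine genes had a lower bound of 1.84, but these were picked for being high.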

How the results depend on the processing

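Chosen after seeing the data were an adjusted p under 0.01, 2-fold and Bonferroni for differences against WT_VILI, KO_VILIlow or KO_noVILI, adjusting again at a mean log2 CPM of at least 1 for those against WT_VILI, a mean of at least 3 for comparisons with WT_noVILI, no filter, variance and reference for sums against WT_noVILI, leaving out X and Y, and leaving out exact zeros. No paired analysis was possible because the tables used here hold no values per library, and for that reason alternatives with other count models, without each replicate or with a replicate block were not run. For the comparisons deposited by the authors, variance scaling, no filter and centring before subtraction do not apply. Depth per library is unknown. No list test changed direction with a call. Of 358 list tests 217 were called, and 48 of these calls were lost at a preset correlation of 0.05, 17 in the rank-based test, 15 against random lists, 14 at a mean log2 CPM of at least 3 and 1 without exact zeros, while 15 were gained in the rank-based test, 28 against random lists and 5 at that mean. Of named gene calls to which each applied, Bonferroni kept 56 and lost 17, centring kept 159 and lost 1, and no filter kept 86 and lost 1.

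Counts moved by more than 1.5 times as follows, by construction for stricter thresholds. At an adjusted p under 0.01 there were 362 genes in KO_noVILI and 1240 in WT_VILI against WT_noVILI, 132 in KO_VILIlow and 215 in KO_VILIhigh against WT_VILI, 7 in KO_VILIhigh against KO_VILIlow, 287 and 310 in the low and high groups against KO_noVILI and 532 in KO_VILIlow against WT_noVILI. Bonferroni adjustment gave 163, 530, 76, 122, 4, 141, 176 and 282 in that order and 310 in KO_VILIhigh against WT_noVILI. A minimum of 2-fold left 306 in KO_noVILI and 689 in WT_VILI against WT_noVILI. Variance multiplied by 0.5 gave 133 in KO_VILIhigh against KO_VILIlow, 1234 and 1477 in the low and high groups against KO_noVILI and 2255 and 2452 against WT_noVILI. Taking the reference as the labels list it gave 210 and 337 against WT_noVILI. Overlaps at 0.01 were 332 for all 3 ventilation responses, 439 for WT_VILI with KO_VILIlow and 382 for both knockout groups. With at least 2-fold in both they were 285 for all 3, 351 for WT_VILI with KO_VILIlow and 333 for WT_VILI with KO_VILIhigh.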

Other observations

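All tests of explanations in this part were chosen after the results were seen. Coagulation and fibrinolysis genes were higher in 6 of 18 cases after ventilation of wild type lungs in the authors' deposited table (6 adjusted over the list alone), with F2rl1 at 1.23. In KO_VILIlow against WT_VILI 4 of 20 were higher (6 adjusted over the list alone), with F5 at 1.47, F7 at 1.32 and Plat at 1.15, and in KO_VILIhigh 5 of 19 (5 adjusted over the list alone), with Plaur at 1.34. The list tests (limma) gave adjusted p = 2.38e-07, 1.88e-06 and 3.49e-07 in that order. Hypoxia genes were higher in 9 and lower in 1 of 25 cases after ventilation of wild type lungs (9 and 2 adjusted over the list alone), with Adm at 2.43, Hk2 at 2.17 and Angptl4 at 1.63 (list test, limma, adjusted p = 0.00011).

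Circadian clock genes were lower as a list in KO_VILIhigh, by the authors' deposited tables. After ventilation of wild type lungs 5 were higher and 6 lower of 21 (6 and 7 adjusted over the list alone), with Nfil3 at 3.32, Dbp at -1.67 and Nr1d1 at -1.46, and the list test (limma) did not pass (adjusted p = 0.514). In KO_VILIhigh against WT_VILI 3 were higher and 3 lower of 21 (5 and 12 adjusted over the list alone), with Bhlhe40 at 1.14, Per3 at -1.61 and Hlf at -1.37 (adjusted p = 0.00478). In KO_VILIlow 1 was higher and none lower of 21 (1 and 1 adjusted over the list alone, list test, limma, adjusted p = 0.369).

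Genes changed alike by genotype without ventilation and in KO_VILIlow numbered 72 in the set tested, Cldn4 left out. A segment flanking Cldn4 would place them beside that gene, and 1 (Hspb1) lay within 100 neighbouring genes on each side, against 1.08 expected. Strain-derived chromosome segments that differ between the animals may account for part of the 72. Chromosome 17 held 14 of them against 3.6 expected, and 8 of these 14 had H2 symbols. The predicted genes Gm11127, Gm7030 and Gm8909 lay among the H2 genes in gene order. They were higher by 6.25, 4.3 and 3.83 in KO_noVILI against WT_noVILI. Off chromosome 17, 12 of 58 had another member within 5 neighbouring genes in GRCm38.p6 order. The upper limit was 8 among 10000 draws of genes called for ventilation. The test was run on 4 gene sets and 1 window. The other sets gave 19 of 72 in the whole set, 15 of 64 without H2 symbols and 11 of 35 alike in all 3 tables. Their limits were 10, 8 and 4. The set without H2 symbols kept Gm11127, Gm7030 and Gm8909, so it did not leave out the whole H2 region. The set off chromosome 17 was taken as deciding after these had been seen. Pairs of related genes such as Ly6k with Ly6e and Ppbp with Cxcl1, shared reads of H2 genes and B cell content (Cd79a, Cd22) stay open.

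Changes between ventilated and unventilated lungs of either genotype cannot be told apart from animal sex, because ventilated groups had male and unventilated groups female levels of Xist and Ddx3y. The same holds for the overlaps of the ventilation responses and for the departures of the genotype difference. Of the genes called in WT_VILI against WT_noVILI, 2.80 percent lay on X or Y, against 3.31 percent of measured genes. Autosomal differences between the sexes could not be measured here.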
